A study of Mus musculus with 6 samples.

How the data were processed

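Per the labels, genomic DNA of whole lungs from 6 mice was amplified in a single PCR step across the vector's guide tag and random barcode, the product was purified from an agarose gel, and the barcodes were sequenced. The submitters' processing notes name FastQC, a read quality tool, and the mouse build mm39. How reads were assigned to guides, how barcodes were merged and how reads were turned into cells is not given in the sources used here. The deposited table, per the file headers, lists for each tumour its guide tag, its barcode, the targeted gene, the mouse and an estimated number of cells. These cell numbers are already scaled: in every mouse 100% of them are whole multiples, within a relative tolerance of 1e-06, of a step of 31.6 to 105 cells. The step was read as the cells represented by 1 read, and the smallest value in each mouse as 2 reads. On that reading the mice had 10.5, 10.7, 11.3, 11.7, 12.8 and 16.4 M reads (M, 1000000), and the minimum of 500 cells corresponded to between 4.78 reads in mouse 6 and 15.8 reads in mouse 5. The reads carry no molecular identifiers beyond the barcode, so read depth limits the detection of small tumours and the resolution of their sizes: in mouse 6, at 105 cells per read, the median tumour of the control and of several targets had the same 941 cells. The replicate is the mouse, not the read.

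The table holds 19 guide tags, 1 for each of the 18 targets and 1 for the non-targeting control, so an effect of a guide outside its target cannot be separated from that of the target. All 18 gene names were matched to mouse symbols through a RefSeq gene table of the assembly GRCm38.p6, by symbol or synonym, in which p300 became Ep300 and FAT1 became Fat1. Since that assembly is not the one the notes name, it was used for names only and no coordinates are given. The virus pool before infection and the editing of the targets in the tumours were not analysed here.

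The labels state no test. Before the data were examined, the design was fixed as follows. Tumours of at least 500 cells entered, and a guide needed 5 such tumours in a mouse. For each mouse and target, 5 measures were taken relative to the control guide of the same mouse, as log2 ratios: the mean size under a log-normal fit, the 50th, 90th, 95th and 99th percentile of size, the share of tumours above the control's 90th percentile with 0.5 added to both counts, the number of tumours, and the summed cells. Each was tested over the 6 mice with limma 3.58.1 in R 4.3.3 (an intercept tested against 0, moderated variances), with Benjamini-Hochberg adjustment over the 18 targets and a threshold of 0.05. For mean size, the 90th to 99th percentiles, the share of large tumours and summed cells, limma pooled the variance of all targets into 90 degrees of freedom. For tumour number and median size it borrowed variance across the targets in part, with 18.3 and 13.2 degrees of freedom. The 18 ratios of a mouse share its control and are not independent. The limma p-values of all measures, those of number and median size included, thus rest on an assumption the data do not meet. An exact two-sided sign-flip test over the mice, which does not need it, stands beside them, and its 64 sign patterns give a smallest p of 0.03125, so after adjustment over the 18 targets it can pass only where at least 12 reach that p. Gene groups were lists fixed in advance; the mean of a list's members minus that of the other targets was tested with the exact sign-flip test over lists with at least 2 members in the pool. Lists for Notch signalling and for the alleles already deleted in the model had 0 members, and those for KEAP1 and NRF2, Hippo signalling and DNA repair had 1 each (Keap1, Fat1 and Atm). Results of 1 target are not reported here; it stays in the adjustments, the pooled variances and the medians over the 18 targets, and a list that holds it was tested but is not given, so targets are counted over the other 17 and each of these is named at least once. Full statistics were reserved for targets past the threshold in mean size, at most 10 in each direction, and for Keap1 whatever its result.

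Alternatives fixed in advance covered the minimum size (none, 100, 1000 and 10000 cells), the reference (the median target of the mouse), the test (exact sign-flip, a bootstrap of mice and then tumours with 2000 draws), weights by tumour number, pooling over mice, removal of barcodes 1 mismatch from a tumour 20 times larger or shared between mice, removal of the largest tumour, other size statistics, equal numbers of tumours, other cut-offs for large tumours, and each mouse left out. For equal numbers, each guide kept its largest tumours, as many as the guide with the fewest had in that mouse. A guide with more tumours thus kept a smaller top share, so this setting favours such guides and does not correct for number. A further 7 were added after the data had been seen: removal of barcodes found in another mouse with at least 100 times as many cells, removal of barcodes within 2 mismatches or 1 insertion or deletion of a tumour 20 times larger, at least 10 reads, removal of barcodes also seen under another guide with more cells, the Cdkn2a guide as reference, barcodes of 20 to 22 bases, and the broader barcode filter together with the median reference. Of all tumours, 911 (3.39%) met the broader barcode filter and 3012 (11.2%) were copies of a barcode with at least 100 times as many cells in another mouse. Sharing at any size was more common: 6075 tumours (22.6%) had a guide and barcode found in more than 1 mouse. Among tumours of at least 500 cells this was 22.1%.

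The procedure was tested on simulated lungs, 50 data sets of 18 targets built from the measured tumours. Targets and control were drawn from all tumours of a mouse with at least 500 cells. A change of size multiplied these sizes, and the minimum was not applied again, so no smaller tumours could cross it. The simulated rates for a change of size, that of the median included, therefore need not hold for the measured lungs. For tumour number against the control, a 1.5-fold change was called in 100% of cases and 5.33% of unchanged targets were called. Unchanged targets were drawn with the control's own expected number, so an equal share of every vector in the virus was built in. The 5.33% therefore does not cover calls that an unequal virus pool would give. For mean size, a 4-fold change was called in 62.0%, a 32-fold change in 100% and 3.33% of unchanged targets, and for summed cells a 4-fold change of size in 92.0% and 5.33% of unchanged targets. The simulated control lacked the spread of the measured one, whose summed cells ranged from 1.32 M in mouse 6 to 96.6 M in mouse 2. With the measured control the limma SE was 0.99 for mean size and 1.07 for summed cells on the log2 scale. The simulated rates for these 2 measures are therefore too high for the measured lungs. With the median target as reference, 28.0% of unchanged targets were called for number and 93.3% for summed cells. All simulated changes went upward and raised the median target, so unchanged targets had mean log2 ratios of -0.0996 for number and -1.25 for summed cells. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plotted with matplotlib 3.10.9.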

Results

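Tuba-seq, a barcoded tumour assay, was applied to the lungs of 6 mice with small cell lung cancer. Each mouse carried alleles that Cre deletes for the tumour suppressors Rb1, p53, p130 and p107, and a Cas9 allele that Cre switches on. A lentiviral pool delivered Cre together with a guide RNA against any of 18 candidate tumour suppressors, or a non-targeting guide that served as the control. An 8-nucleotide tag in the vector names the guide and a random barcode marks each infected cell and its descendants, so the barcode reads of a lung list its tumours and estimate how many cells each contains. Each mouse received 970000 infectious units, and lungs were collected at the survival end point, at a median of about 13 weeks. The 6 mice formed a single group, with the mouse as the replicate, and every comparison set a target's guide against the control guide in the same lung.

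The table held 26839 tumours, between 3325 and 5955 per mouse, from 10.5 to 16.4 M barcode reads per mouse (M, 1000000). Of these, 12198 tumours had at least 500 cells and entered the comparisons. The estimated tumour cells of a lung summed to between 357 and 1115 M. A small number of tumours held most of them: 820 tumours of at least 1000000 cells, 3.06% of the total, contained 88.8% of all cells, whereas the 14641 tumours under 500 cells contained 0.0770%. The control guide had 50 to 151 tumours of at least 500 cells per mouse, with a median size of 1413 ± 581 cells (SD, n = 6). Summed control cells ranged from 1.32 M in mouse 6, where the largest control tumour had 0.456 M cells, to 96.6 M in mouse 2. All measures are relative to this control, so its spread enters each of them. Loss of the targeted genes in the tumours is not analysed here.

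The first comparison asked which targets altered the number of tumours. The guide against Keap1, the adaptor through which the transcription factor NRF2 is marked for degradation, gave 241 ± 107 tumours per lung, and that against Crebbp, a histone acetyltransferase, gave 142 ± 57.7, against 95.7 ± 39.5 for the control (SD, n = 6). Relative to the control, Keap1 tumours were 2.5-fold more numerous (95% CI 2.20 to 2.84) and Crebbp tumours 1.48-fold (1.32 to 1.67), each higher in 6 of 6 mice. At the other end, tumours with the guide against Foxo3, a forkhead transcription factor restrained by AKT, fell to 0.583-fold (0.522 to 0.651) and those against Atm, the kinase that responds to DNA double-strand breaks, to 0.641-fold (0.567 to 0.724), both lower in 6 of 6 mice.

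For Keap1, the gene named in the study's title, the log2 number ratio was 1.32 ± 0.09 (SE, n = 6 mice; limma adjusted p = 8.6e-11; exact two-sided sign-flip p = 0.03125). Over the 17 targets counted here, limma with Benjamini-Hochberg adjustment placed 17 past the threshold of 0.05, 5 higher and 12 lower than the control, and the exact sign-flip test, whose smallest possible p with 6 mice is 0.03125, placed 11 past it, 2 higher and 9 lower after the same adjustment. The count depended on the reference: set against the median target of each mouse, 5 targets were higher and 6 lower by limma. With that reference the exact sign-flip test passed none of the 17, with a lowest adjusted p of 0.0625. The 5 higher ones were Keap1, Crebbp, Atrx, Kmt2d and Apc, and the 6 lower ones Foxo3, Atm, Stk11, Cdkn2a, Setd2 and Fat1. Crebbp is described in detail here because of its values, which had been seen when it was picked.

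Among the 6 chromatin regulators, 3 targets were higher and 3 lower than the control by limma, both over all targets and when adjusted over the list alone. This split depended on the reference and the test: against the median target Ep300 (limma adjusted p = 0.548) and Arid1a (0.0836) did not pass, and by the exact sign-flip test against the control only Crebbp and Setd2 did (adjusted p = 0.0469 each). Ep300 fell to -0.16 without mouse 1 (limma adjusted p = 0.0703), and leaving out single mice also ended the calls of Atrx, Kmt2d, Apc and Smad4. Beside Crebbp, the log2 number ratio was 0.22 ± 0.09 (SE) for Atrx, a chromatin remodeller, and 0.20 ± 0.08 for Kmt2d, a histone H3 lysine methyltransferase, whereas it was -0.29 ± 0.11 for Ep300, the close relative of Crebbp, -0.40 ± 0.09 for Arid1a, a SWI/SNF subunit, and -0.49 ± 0.09 for Setd2, another histone methyltransferase (limma, n = 6 mice). The value for Atrx turned to -0.019 when tumours of 100 cells or more entered. Tumours with the guide against Stk11, the kinase upstream of AMPK, were at 0.670-fold the control (0.588 to 0.763). Cdkn2a, which encodes inhibitors of the cell cycle, and Fbxw7, the substrate receptor of a ubiquitin ligase, were at 0.699-fold and 0.830-fold. The cell-surface genes Fat1, an atypical cadherin, and Ptprd, a receptor tyrosine phosphatase, were at 0.722-fold and 0.818-fold. In the WNT and TGF-beta list, Apc was at 1.14-fold and Smad4 at 0.788-fold, and Spop, a ubiquitin ligase adaptor outside the lists, was at 0.862-fold.

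The labels describe an equal mix of vectors, but the composition of the virus pool was not measured in the data used here, so differences in number can also come from the pool. Under 500 cells, Keap1 tumours were 1.88-fold and Crebbp tumours 1.03-fold as numerous as control tumours. In tumours of at least 10000 cells, 2 targets remained past the threshold, both higher: Keap1 at 2.79-fold and Crebbp at 2.04-fold.

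**Figure D1:**
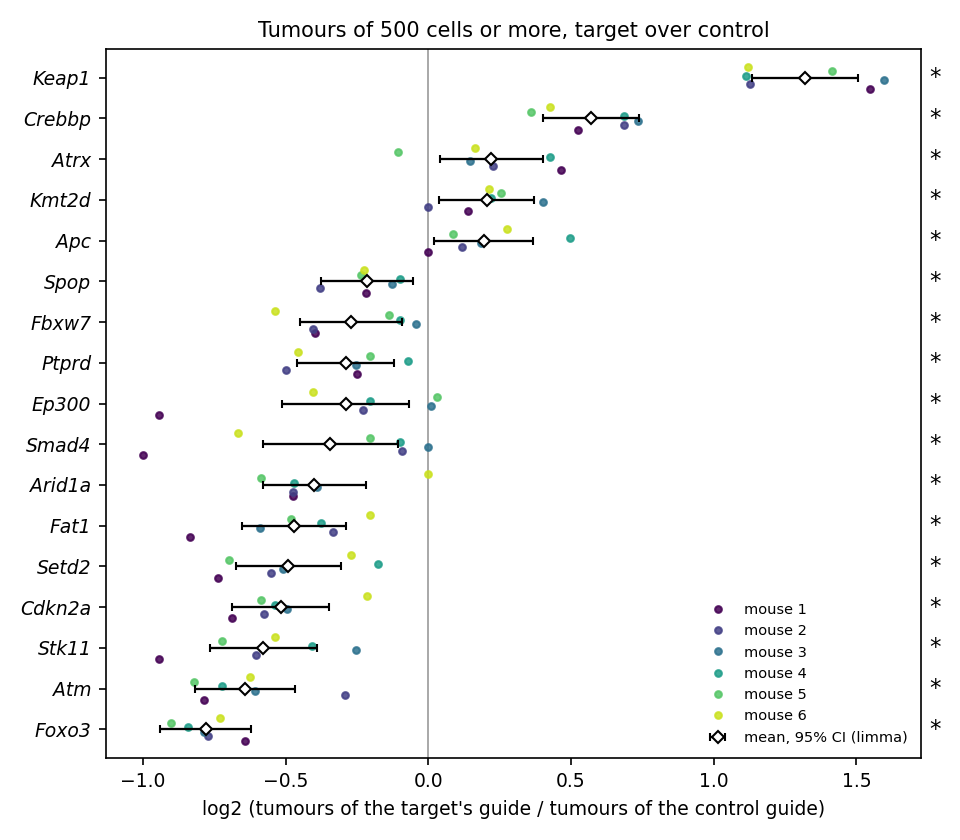
Number of tumours of at least 500 cells for each of 17 targets relative to the control guide in the same lung, on a log2 axis; coloured points are the 6 mice, diamonds and bars the mean and 95% confidence interval from limma, and asterisks mark an adjusted p under 0.05. All 6 mice lie above 0 for Keap1 and Crebbp, and all 6 lie below 0 for Foxo3 and Atm.

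The second comparison asked whether tumours with a given guide were larger. The median tumour of the Crebbp guide was 1.75 times as large as that of the control (95% CI 1.31 to 2.34; log2 ratio 0.81 ± 0.19 SE, n = 6 mice, limma adjusted p = 0.0099). It was higher in 6 of 6 mice, with an exact sign-flip p of 0.03125, the smallest possible. In mouse 6 the medians were 1046 cells for Crebbp and 941 for the control, at 105 cells per read. That mouse, and with it the p of 0.03125, thus rests on a difference at the resolution of size. After adjustment over the 18 targets the exact test can pass only where at least 12 reach that p. It therefore cannot single out a few targets in this or the later measures. The call depended on the minimum size, with log2 ratios of 0.35 from 100 cells (limma adjusted p = 0.0659), 0.17 from 1000 cells (0.825), -0.50 from 10000 cells (0.970) and 0.50 from 10 reads (0.208). It was also lost by the bootstrap (log2 ratio 0.67, adjusted p = 0.189), without copies in other mice (0.78, limma adjusted p = 0.161), without mouse 2 (0.71, limma adjusted p = 0.0611) and without mouse 3 (0.81, limma adjusted p = 0.0547). The other 16 targets counted here did not pass the threshold. The median Keap1 tumour had 1618 ± 403 cells (SD, n = 6) against 1413 ± 581 for the control, a log2 ratio of 0.25 ± 0.17 (SE; 95% CI -0.12 to 0.62; limma adjusted p = 0.509), higher in 5 of 6 mice. The Keap1 ratio was 0.36 with no minimum, where it passed (limma adjusted p = 0.0317), -0.25 from 1000 cells and 1.43 from 10000 cells, where it did not.

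Mean size, estimated from a log-normal fit, passed for 0 of the 17 targets by limma, with 0 at an unadjusted p under 0.05. For Stk11 the log2 ratio was 1.87 ± 0.99 (SE, n = 6 mice; 95% CI -0.09 to 3.83; limma adjusted p = 0.550), higher in 4 of 6 mice, and it was 0.93 without mouse 1 and 0.48 with no minimum size. In mouse 1 the fitted mean of Stk11 was 12684900 cells, although its 26 tumours summed to 39.0 M cells, so the fit there lay far above the arithmetic mean. The fitted mean of Keap1 tumours was 449714 ± 572951 cells (SD, n = 6) and that of the control 189957 ± 179525, a log2 ratio of 1.23 ± 0.99 (SE; 95% CI -0.72 to 3.19; limma adjusted p = 0.958; exact sign-flip p = 0.281), higher in 5 of 6 mice. The Keap1 ratio was 0.54 without mouse 6, 2.08 without mouse 5, 0.21 without barcodes shared between mice and 3.31 with equal numbers of tumours. For equal numbers only the largest tumours of each guide were kept, which favours guides with more tumours, such as Keap1. Setd2 and Spop had the lowest estimates, -0.98 and -0.95, but that of Setd2 rested on mouse 1 (-5.71) and was -0.03 without it. Upper percentiles of size gave 0 targets at the 90th, 95th and 99th, and the share of tumours above the control's 90th percentile gave 0, with 0 targets at an unadjusted limma p under 0.05 in each. In tests on simulated lungs, a 4-fold change of size in a target was called in 62.0% of cases for the mean and in 100% for the median. There the minimum of 500 cells was not applied again after sizes had been changed. For the 17 targets counted here the 95% intervals of the median end at a log2 ratio of 1.23 (Crebbp) or lower. These medians cover only tumours of at least 500 cells, and 54.6% of all tumours were smaller. Tumours that cross the minimum can make the shift of this median smaller than the change of size. The intervals and the simulated rate therefore do not exclude a 4-fold change of size.

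Gene groups were compared by mean size within each mouse. Targets of the cell-surface list, Ptprd and Fat1, lay at -0.70 on the log2 scale from the remaining targets (SD 0.78, n = 6), lower in 6 of 6 mice. The exact sign-flip p was 0.03125 and the adjusted p 0.0781 over the 5 lists tested, and 0 of the 4 lists given here passed. The value was -0.42 without mouse 1, -0.14 with the arithmetic mean (2 of 6 mice above 0), -0.06 from 10000 cells and -1.16 with equal numbers of tumours. That last setting kept the largest tumours of each guide and so favours guides with more tumours. The chromatin list stood at -0.38 (SD 0.41, adjusted p = 0.208), Cdkn2a and Fbxw7 at -0.42 (SD 0.97, adjusted p = 0.430) and Apc and Smad4 at -0.34 (SD 1.13, adjusted p = 0.5), by the same exact test; without mouse 1 the last 2 were -0.75 and -0.005, and Cdkn2a and Fbxw7 turned to 0.31 with the arithmetic mean and 0.36 from 10000 cells. With 6 mice a list can pass only if at least 4 of the 5 lists reach the smallest p.

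**Figure D2:**
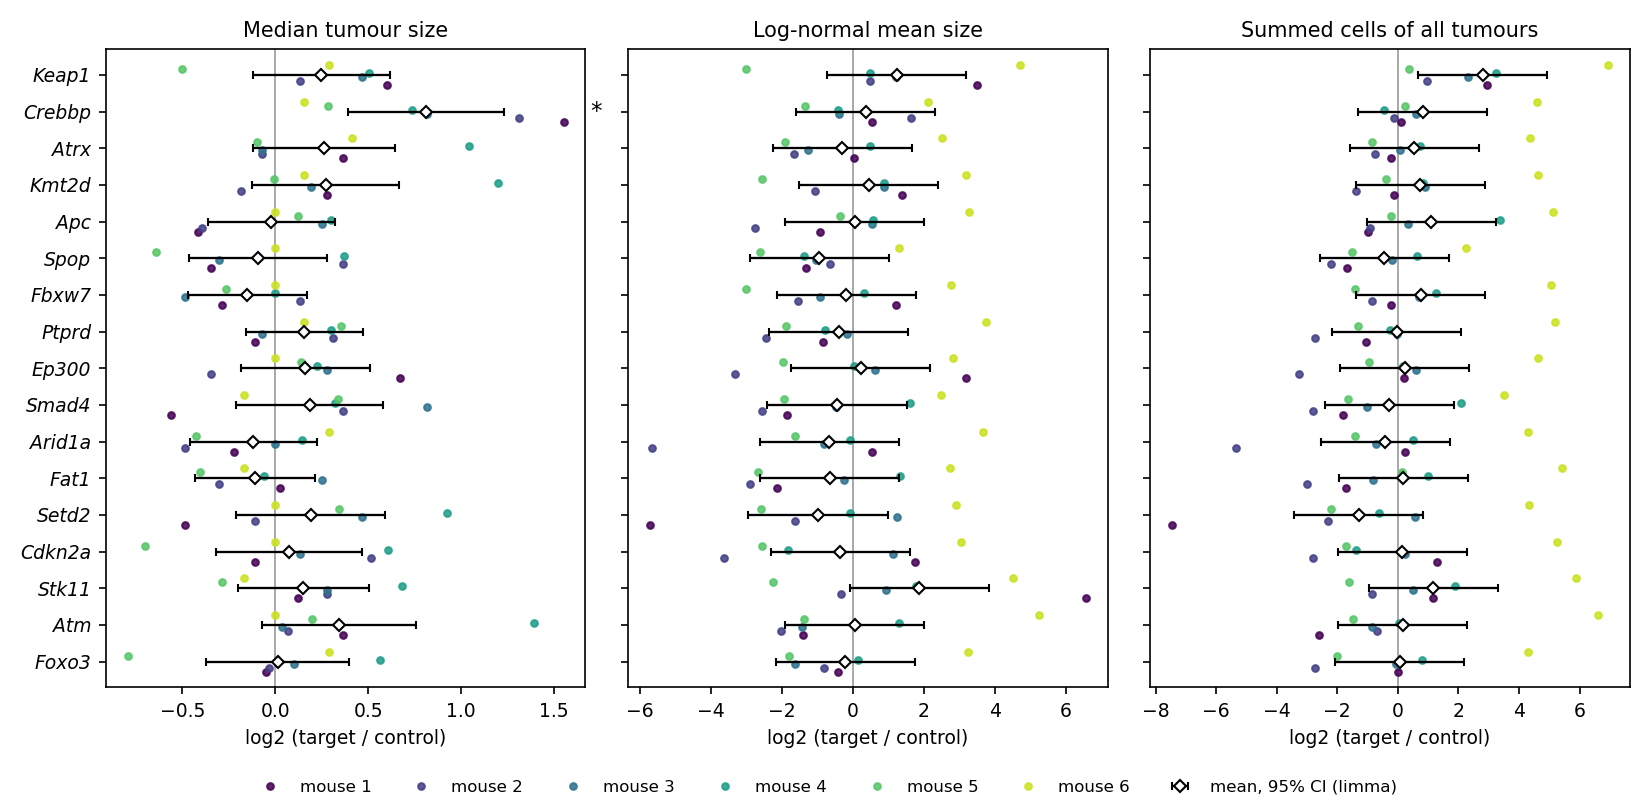
Median tumour size, log-normal mean size and summed cells of each of 17 targets relative to the control in the same lung, on log2 axes with a different scale in each panel; points are the 6 mice, diamonds and bars the mean and 95% confidence interval from limma, and asterisks mark an adjusted p under 0.05. Crebbp passes for the median only, and in mouse 6 all 17 targets shown lie above the control in mean size and in summed cells.

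The third comparison combined number and size as the summed cells of all tumours with a guide. Keap1 tumours held 123 ± 60.7 M cells per lung (SD, n = 6), 16.8% ± 5.36 of all tumour cells. The control held 30.4 ± 34.6 M, or 4.31% ± 3.63. Against the control, summed cells were 6.93-fold higher for Keap1 (95% CI 1.59 to 30.3; log2 ratio 2.79 ± 1.07 SE, limma adjusted p = 0.0958), in 6 of 6 mice with an exact sign-flip p of 0.03125. This did not pass the adjusted threshold, which 0 of the 17 targets did by limma, while 1, Keap1, had an unadjusted p under 0.05 by either test.

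The interval was narrower with another reference. Set against the median target of each mouse, the standard error for Keap1 was 0.27, and its summed cells were 5.16-fold higher (limma adjusted p = 0.00010; exact sign-flip p = 0.03125, the smallest possible), again in 6 of 6 mice. Without mouse 6, whose control had the fewest cells, Keap1 stood at a log2 ratio of 1.97 against the control (limma adjusted p = 0.0550), and without barcodes shared between mice at 1.80 (0.149). The remaining targets counted here ranged from -1.29 for Setd2 to 1.16 for Stk11 on the log2 scale, and for none of these 16 did the 95% interval exclude 0. Single mice carried both ends, since Setd2 was at -0.05 without mouse 1 and Stk11 at 0.22 without mouse 6.

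Tumour counts by size class, a comparison chosen after the data had been seen, were also set against the median target. From the smallest class to the largest, with edges at 500, 1000, 10000, 100000 and 1000000 cells, Keap1 tumours were 2.35, 2.38, 3.2, 2.01, 2.08 and 4.13-fold as numerous, in 6 of 6 mice except from 100000 to under 1000000 cells (5 of 6, exact sign-flip p = 0.0625). Crebbp tumours were 1.29, 1.36, 1.73, 2.08, 1.86 and 1.57-fold as numerous, in 6 of 6 mice except from 500 to under 1000 cells (5 of 6, exact sign-flip p = 0.0625) and at 1000000 cells or more (4 of 6, exact p = 0.125). Foxo3 tumours were fewer than those of the median target in 6 of 6 mice in each of the 4 classes below 100000 cells, from 0.818-fold under 500 cells to 0.610-fold from 10000 to under 100000 cells, and were 0.571-fold (exact sign-flip p = 0.125) and 0.674-fold (exact p = 0.0625) in the classes above. Against the control the Foxo3 log2 ratio was -0.62 under 500 cells and -0.65 from 10000 to under 100000 cells. Values with 6 of 6 mice on the same side had the smallest possible exact sign-flip p, 0.03125, and are given without adjustment, since none of the 108 combinations of target and class could pass unless at least 68 reached it.

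**Figure D3:**
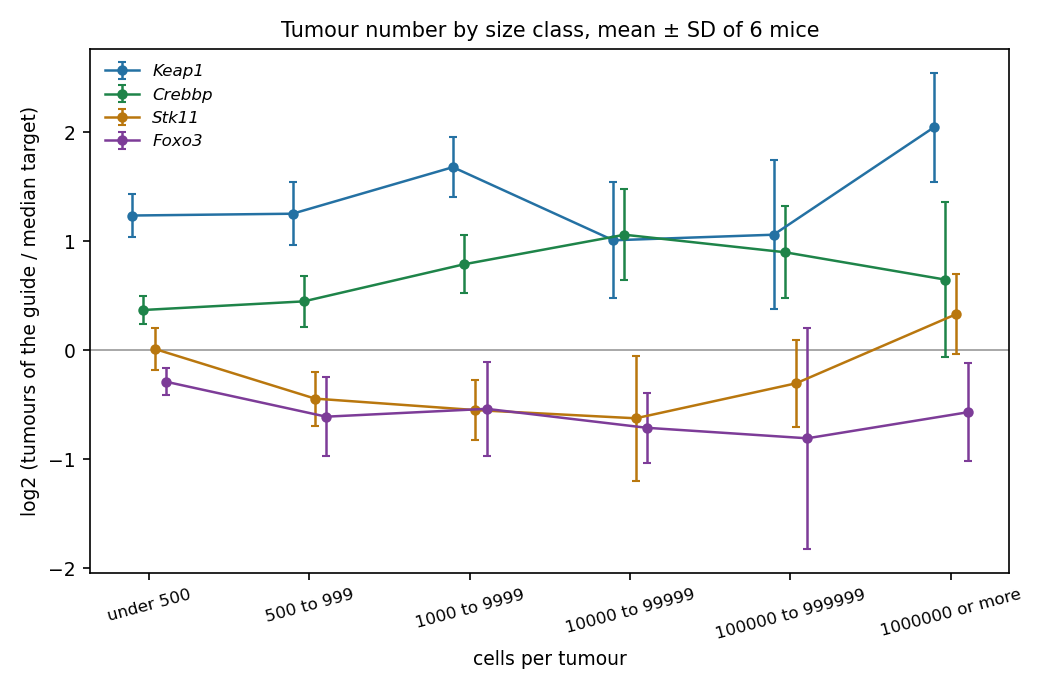
Number of tumours in each size class for 4 guides relative to the median target of the same lung, on a log2 axis; points and bars are the mean and SD of 6 mice. Keap1 is highest at 1000000 cells or more, at 2.04, and Crebbp from 10000 to under 100000 cells, at 1.06.

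Agreement between mice differed by measure. Across the 17 targets, the log2 number ratios of any 2 mice correlated with a median Pearson r of 0.87 over 15 pairs (0.82 to 0.97; median Spearman rho 0.72), those of summed cells with 0.38 (0.21 to 0.61; rho 0.27) and those of mean size with 0.10 (-0.26 to 0.42; rho -0.02). These correlations run across targets, which are not independent replicates. The mice also received the same virus pool, whose composition was not measured. An unequal share of vectors would raise the agreement in number without any effect of the targets.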

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

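The tests of the virus pool and of barcodes copied between mice, and the choice to repeat the mouse 6 draws without copies and misread barcodes, came after the results they bear on had been seen. The swaps, the first draws and the test of barcode errors were set down before their results.

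The Keap1 guide gave more tumours than the control not only among the tumours compared above but also among the 14641 tumours under 500 cells, which the main design leaves out: the log2 number ratio there was 0.91 ± 0.28 (SD, n = 6 mice). An unequal mix of vectors in the virus would raise small and large tumours alike, and the ratio at 10000 cells or more exceeded that under 500 cells by 0.57 ± 0.24 (SE, 5 of 6 mice, exact sign-flip p = 0.0625), or by 0.79 ± 0.23 without barcode copies and misread barcodes (6 of 6, exact p = 0.03125). With the median target in place of the control the same differences were 0.25 ± 0.22 (SE, 4 of 6 mice, exact p = 0.344) and 0.49 ± 0.22 (5 of 6, exact p = 0.0938), so a larger share of the virus and an effect of Keap1 loss cannot be told apart, because the difference depends on the reference and on the barcode filter. Barcodes of large tumours that turn up as small copies in other mice account for little of the excess, since the mean log2 ratio of Keap1 was 1.25 without them, and the same holds for sequencing errors in barcodes, since it was 1.32 without barcodes close to those of far larger tumours. For Crebbp the log2 ratio was 0.04 ± 0.29 (SD) under 500 cells and the difference 0.99 ± 0.20 (SE), or 1.09 ± 0.15 without those barcodes, and with the median target 0.67 ± 0.19 and 0.78 ± 0.18, each in 6 of 6 mice (exact p = 0.03125, not adjusted over targets), which argues against the pool as the whole cause of its excess.

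Tumour number placed 17 targets past the threshold, and 1 of the 32 ways of swapping target and control within mice, the real one, gave as many, with 0 as the highest of the others. For median size the real count was 1, Crebbp, reached by 1 of the 32 swaps, again the real one, with 0 as the highest of the others. Both counts stood at the smallest share that 32 swaps can give. For number, the swaps argue against chance assignment within mice. Each swap turned all targets of a mouse together, and an unequal virus pool shared by the mice could give the same result. The swaps therefore do not tell an effect of the targets from one of the pool. For median size the share rests on 1 target. Its call was not reached by the bootstrap (adjusted p = 0.189) or by the exact sign-flip test (adjusted p = 0.281), which cannot pass for 1 target alone. Chance is therefore not excluded for median size.

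In mouse 6 the summed cells of all 17 targets counted here exceeded those of the control, which had 151 tumours of at least 500 cells but 1.32 M cells in all, and 0 tumours of at least 1000000 cells where the other mice had 3 to 10. A chance lack of large tumours among the control's was tested by drawing as many tumours at random from the lung: the drawn sets held 50.8 M cells at the median, and p for as few cells was 1e-05, the smallest that 100000 draws can give. The drawn sets include guides with more cells than most, such as Keap1, which lowers this p. The draws were repeated once 16 copies and misread barcodes had been left out of the control. The 135 control tumours left held 1.31 M cells, against 50.8 M at the median of the drawn sets. The p of these draws was 0.0001, the smallest that 10000 draws can give. Leaving out so few small tumours could hardly bring the control near the drawn sets, so this p adds little. The values show only that the tumours found by these filters were too few to account for the low sum. No biological explanation was tested, because the design gives none, and the value stays open.

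Dixon's test was run on 74 sets of 6 mice and picked out 9 values, where about 3.7 arise by chance, and 6 of these 9 were in mouse 6 and share its control. In mouse 2 the control's summed cells stood apart at 96.6 M. In mouse 6 the log2 mean size ratio of Ptprd was 3.75, the log2 number ratio of Arid1a was 0, and the log2 ratios of summed cells were 6.60 for Atm, 4.36 for Atrx, 4.58 for Crebbp and 5.18 for Ptprd. In mouse 4 the log2 ratios of median size were 1.39 for Atm and 1.2 for Kmt2d.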

How the results depend on the processing

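Of the alternatives, 7 were chosen after the data had been seen (barcode copies, the broader barcode filter, 10 reads, barcodes under another guide, the Cdkn2a reference, barcode length, and the broader filter with the median reference), and the 1-mismatch filter removed 0 tumours. Over 580 values of single targets, 484 kept their direction and side of the threshold or were short of it both times, 76 kept their direction but lost the call, 7 gained it and 13 changed sign with a call on either side. The 484 include 23 values pooled over mice, which had no test and were counted there for lying within the SD of the main value. They also include 23 values of the 1-mismatch filter, which could not differ from the main ones. Keap1 and Crebbp stayed past the threshold in tumour number in each setting that gave a test, with log2 ratios of 1.07 to 1.84 and 0.26 to 1.09. The count for tumour number fell from 17 to 2 at 10000 cells or more, to 7 against the Cdkn2a guide (6 higher, 1 lower), and to 11 against the median target with and without the broader filter (5 higher, 6 lower), by the exact sign-flip test and the bootstrap (2 higher, 9 lower) and without barcodes shared between mice (4 higher, 7 lower), and was 14 to 17 without each mouse in turn. Against Cdkn2a, whose own number was below that of the control, the log2 ratios turned to 0.12 for Arid1a, 0.23 for Ep300, 0.046 for Fat1, 0.25 for Fbxw7, 0.23 for Ptprd, 0.026 for Setd2, 0.17 for Smad4 and 0.30 for Spop. Spop was at 0.012 against the median target and at 0.025 with the broader barcode filter added, and Atrx at -0.066 with no minimum and at -0.019 from 100 cells. Mean size, with 0 calls in the design fixed in advance, had 1 (Crebbp) without barcodes shared between mice and 0 without each mouse. Median size, with 1 call (Crebbp), had 5 with no minimum (4 higher, 1 lower), 0 from 100, from 1000 and from 10000 cells, from 10 reads, by the bootstrap and without copies in other mice, 0 by the exact sign-flip test, which cannot pass for 1 target alone, and 0 to 1 without each mouse; the ratio of Crebbp was -0.50 from 10000 cells. The 90th percentile and the share of large tumours had 1 call each (Crebbp) with no minimum. Summed cells had 1 (Keap1) against the median target, against Cdkn2a, by the bootstrap, weighted by tumour number and with the broader filter and the median reference, and 0 without each mouse. Fewer tumours and a higher floor account by construction for part of the calls lost at 10000 cells; the cause of the other changes was not tested. Gene groups had 0 of the 4 lists given past the threshold in every setting run with 6 mice, and without each mouse the smallest exact p is 0.0625, so none could pass there; other references cancel in that comparison, and weights, the bootstrap, pooling and limma were not run for it. Depth limits the smallest tumours, since 500 cells were 4.78 to 15.8 reads.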

Other observations

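The tests in this part were chosen after the data had been seen, apart from the share of large tumours for Keap1 and the tumour number and 95th percentile of Stk11, which the design fixed in advance. Of the 346 Keap1 tumours with at least 10000 cells, 38.4% had at least 1000000 cells, and in the mean over mice this share was 39.6% ± 10.2 (SD, n = 6). Against the median target, the odds of reaching 1000000 cells were 1.92-fold for Keap1 and 1.73-fold for Stk11, each higher in 6 of 6 mice with an exact two-sided sign-flip p of 0.03125, the smallest possible, which adjustment over 18 targets could not pass unless at least 12 reached it. Against the control guide, Keap1 was higher in 5 of 6 mice (exact p = 0.0938) and Stk11 in 4 of 6 (exact p = 0.281). The share of all Keap1 tumours above the control's 90th percentile was 1.22-fold that of the median target, higher in 4 of 6 mice (exact p = 0.25, limma adjusted p = 0.548).

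Crebbp and Ep300 encode closely related acetyltransferases, and their guides were compared directly. Crebbp tumours were 1.81-fold more numerous than Ep300 tumours and 1.57-fold larger at the median, each in 6 of 6 mice (exact p = 0.03125, adjusted p = 0.0536 over 12 comparisons of guides, where at least 8 would have to reach the smallest p for any to pass), and at the 95th percentile of size the ratio was 0.773-fold, with an SD of 1.47 on the log2 scale (exact p = 0.531). Stk11, with fewer tumours than the median target in 6 of 6 mice, had a 95th percentile of size 2.19-fold that of the median target, also in 6 of 6 (limma adjusted p = 0.0809), and against the control guide 2.88-fold, higher in 4 of 6 (limma adjusted p = 0.996), with the log2 ratio falling from 1.53 to 0.54 without mouse 6.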
